A study of Mus musculus with 4 samples.

How the data were processed

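Messenger RNA was measured in cells isolated as microglia, the resident macrophages of the brain, from mouse embryos at embryonic day 14. Hat1, which encodes a histone acetyltransferase, had been deleted conditionally with Cre recombinase and loxP sites, per the series' design text. The 4 libraries carry the titles ko or ff with a number. They were grouped by that title into ko (numbers 1 and 3) and ff (numbers 2 and 5), with 2 libraries in each group. The labels do not spell out ff, name the Cre driver or name the deleted exons, and ff is taken here as the comparison group. Nothing in the labels says whether a library came from 1 embryo, several or a litter, so the p-values measure the spread between these libraries.

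Total RNA was extracted with TRIzol and poly(A) RNA was selected with oligo(dT) beads, per the labels' protocols. Reads were 150-bp pairs handled with CASAVA, filtered for adapters, undetermined bases and low quality, and aligned with HISAT2 2.0.5, per the series' design text. The build was GRCm39, per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited table holds whole-number counts per gene made by the authors, with no normalization. The design text speaks of FPKM and of DESeq2 with an adjusted p of at most 0.05. The table used here holds counts, so the count test fixed for that case was used.

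The table had 26054 lines below its header. Of these, 3 held stray annotation text without counts and were left out, and 26051 features remained. Total counts per library ran from 14814846 to 18990917. Libraries of a group differed by more than sampling noise, with chi-square values of 7.73 (ff) and 14.8 (ko) times their degrees of freedom. Genes with too few counts were removed with edgeR's filterByExpr, which left 15840 genes holding 99.85% of the counts. Counting precision follows from these depths, and intervals and floors given for single ratios cover counting error only. A group whose libraries were all at 0 was given a floor of 3 counts over the group, 0.0975 CPM. A ratio to that floor leaves out the counting error of the other group.

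Counts were scaled with trimmed mean of M-values factors, which lay between 0.991 and 1.01, and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Expression is given as CPM on the scaled library sizes, as mean ± SD, and log2 fold changes are ko minus ff with standard errors. With 2 libraries against 2, an exact two-sided permutation test could give no p under 0.333, so the test leans on the spread shared across genes. On counts simulated at the same depths with 15512 genes tested, the test recovered 29.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 89.4% of those changed 4-fold. It made 158 calls there, of which 28 were false, a larger share than the nominal threshold allows. limma-voom made 133 calls with 13 false and DESeq2 141 calls with 18 false on simulated counts.

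Gene lists for microglial states, macrophage functions, chromatin, metabolism, stress and other cell types were written before the data were examined. The 35 lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance in 1 direction, were run beside it. In simulated counts a list of 30 genes shifted by 0.5 on the log2 scale had an adjusted p of 3.34e-09 with the preset correlation and 0.565 with an estimated one. Of 30 unshifted lists 0 passed with the preset correlation. The simulated genes were drawn independently, so this cannot show how the preset performs on lists whose genes move together. Intervals of list medians are bootstrap intervals over genes from 10000 draws. They treat the genes of a list as independent and leave out the spread between libraries.

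Genes are named by a rule also fixed beforehand. It takes Hat1, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and groups apart, up to 4 members past the threshold from each list, and up to 2 of the most expressed members of each list with none. Symbols of the Gm and Rik kinds and pseudogenes were left out of the largest changes, with gene types matched by symbol to RefSeq on GRCm38. Symbols of the LOC kind were not left out, and LOC118567825 had no match there, so its type was not checked. Any other gene named was chosen after its values were seen. The reference in use was of another build than the counts, so no coordinates are given. It served only for gene types and for transcript length and GC content.

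The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no scaling, no filter, a filter of 50 counts in each of 2 libraries, a fold threshold of 2 and each library left out in turn. An offset for transcript length and GC content was added after the data were seen.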

Results

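Gene expression was measured by RNA sequencing in cells isolated as microglia from embryonic day 14 mice, in 2 libraries titled ko and 2 titled ff. The title of the series places the study in the control of cortical neural stem cells by Hat1 in microglia. The comparison asks which transcripts differ in these isolates when this histone acetyltransferase is deleted. The libraries held 14814846 (ff library 2), 15970403 (ff library 5), 18990917 (ko library 1) and 15747757 (ko library 3) counts.

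Hat1 (feature gene-Hat1) had 650 and 1149 counts in ff libraries 2 and 5, and 737 and 581 counts in ko libraries 1 and 3. This came to 57.8 ± 19.1 CPM (counts scaled to the library total) in ff and 37.9 ± 1.84 in ko (SD, n = 2 each). The log2 fold change was -0.61 ± 0.23 (SE) and did not pass the threshold, with an adjusted p of 0.298 by the edgeR test. The ff libraries themselves lay apart, at 44.3 and 71.4 CPM. Without ff library 2 the log2 fold change was -0.91 with an adjusted p of 0.00286, and without ff library 5 it was -0.25 with an adjusted p of 0.535. Without ko library 1 it was -0.67 with an adjusted p of 0.000114, and without ko library 3 it was -0.57 with an adjusted p of 0.612. A count over the whole gene can include transcripts that lack the deleted exons, which the labels do not name, so it checks the ko titles only in part.

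The libraries also differed in sex-linked transcripts. Ko library 1 held 3188 counts of Ddx3y, 1057 of Uty, 459 of Kdm5d and 1309 of Eif2s3y, all on the Y chromosome, and 3 of Xist, the transcript of the inactive X chromosome. The other 3 libraries held 2847, 3646 and 3986 counts of Xist and at most 1 count of any of these Y-linked genes. Across 15840 genes the log2 values of ff libraries 2 and 5 had a Pearson correlation of 0.986 and those of ko libraries 1 and 3 of 0.979. Correlations between groups ran from 0.970 to 0.981, and that of ff library 5 with ko library 3 lay above that of the 2 ko libraries. These are correlations across genes, which are not independent replicates. The first principal component held 51.5% of the variance and put both ff libraries on the negative side and both ko libraries on the positive side. The second held 29.1% and cut across the groups. It put ff library 2 and ko library 1 on the positive side, at 17.75 and 22.14. On the negative side were ff library 5 and ko library 3, at -6.16 and -33.72.

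The libraries of the ko group had 188 genes higher and 82 genes lower than those of the ff group, 270 of the 15840 tested. The lists of the interferon response and of class I antigen presentation held 44 of the higher genes (23.4%), and C-type lectin genes of the Cd209 family were among the deepest falls. Rises of at least 2-fold were found in 97 genes and falls of that size in 13. Both ko libraries lay on the same side of both ff libraries in all 270 genes. Over all tested genes 49.6% had groups apart in this way, where chance gives 33.3%. DESeq2 also called 181 of the higher and 81 of the lower genes. The number of calls depended on single libraries, with 198 genes called without ff library 2 (143 higher, 55 lower), 450 without ff library 5 (215 higher, 235 lower), 996 without ko library 1 (411 and 585) and 1213 without ko library 3 (860 and 353). It was 566 with DESeq2, 175 with limma-voom and 1386 without a filter on low counts. Simulated counts at this depth gave more false calls than the threshold allows, 28 of 158.

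**Figure D1:**
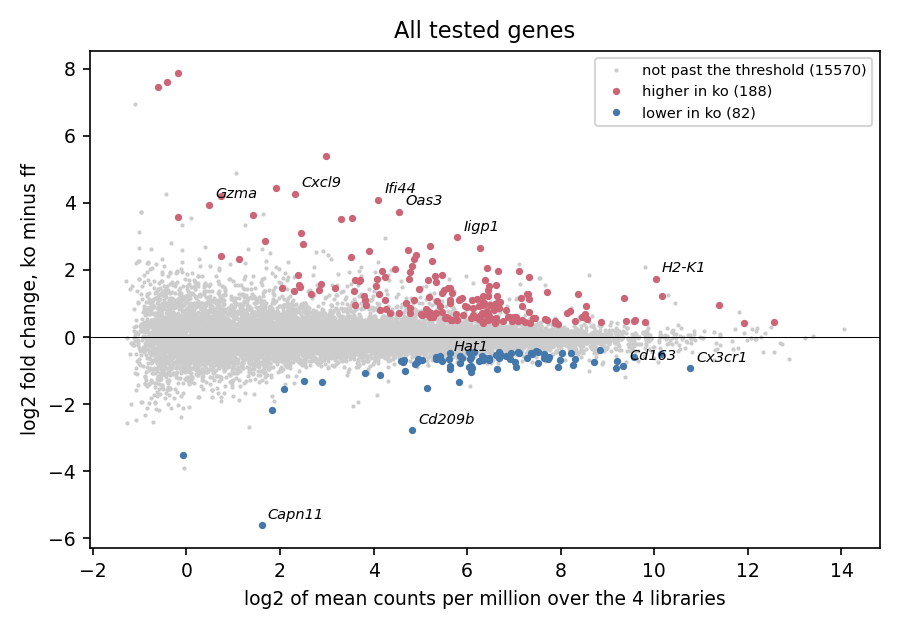
Each point is 1 of 15840 tested genes, with the log2 of its mean CPM over the 4 libraries on the horizontal axis and the log2 fold change of ko minus ff on the vertical axis. The 188 genes higher in ko are red and reach larger changes than most of the 82 lower genes in blue, and the 3 red points above 7 are fitted values of genes with 0 counts in both ff libraries.

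Interferon-stimulated genes rose together in the ko libraries. Of 32 tested members of the interferon response list, 31 rose and 0 fell, and all 32 rose when adjusted over the list alone. Their median log2 fold change was 1.73 (95% interval 1.45 to 1.96), or 3.31-fold. Ifi44, a cytoplasmic protein induced by interferon, rose from 1.89 ± 0.217 to 32.4 ± 1.19 CPM (SD, n = 2 each), a log2 fold change of 4.10 ± 0.18 (SE) with an adjusted p of 6.3e-05. Oas3, an oligoadenylate synthetase that senses double-stranded RNA, rose from 3.23 ± 0.615 to 43.4 ± 0.737. Oasl1, of the same family, rose from 9.74 ± 1.43 to 63.7 ± 1.28, and the chemokine Cxcl10 from 1.42 ± 0.274 to 9.91 ± 1.06. The list passed camera with an adjusted p of 4.96e-40, and had an adjusted p of 0.299 with an estimated correlation and of 0.00726 by fry. Without ko library 1, the library with Y-linked transcripts, the median log2 fold change was 1.67. In the same comparison the markers of lymphocytes and of mural cells and fibroblasts had median log2 fold changes of 0.66 and 0.77, with 1 and 0 of 17 genes past the threshold and an adjusted p of 0.712 for each list with an estimated correlation. The mural median was 0.48 without ff library 2, with an adjusted p of 0.184, and the lymphocyte median was 0.40 without ff library 5.

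Class I antigen presentation rose as well. Of 18 tested members, 13 rose and 0 fell, and 17 rose when adjusted over the list alone. The median log2 fold change was 1.14 (95% interval 0.67 to 1.49). H2-K1, a classical class I heavy chain, rose from 480.4 ± 12.8 to 1604 ± 33.2 CPM (SD, n = 2 each), or 3.34-fold, with an adjusted p of 6.3e-05. Nlrc5, a transactivator of class I genes, rose from 7.32 ± 0.160 to 28.9 ± 1.61. H2-Q7 had 3 and 2 counts in ff and 56 and 53 in ko, a ratio of 19.4 with an exact counting interval of 8.05 to 60.8. H2-Q6 had 0 counts in both ff libraries and 51 counts over both ko libraries, 15.1-fold the floor of 3 counts over the group. Its call was lost without ff library 2, where the adjusted p was 0.0564. The list median with H2-Q6 at its ratio to the floor was also 1.14. Camera gave an adjusted p of 1.52e-18, against 0.299 with an estimated correlation and 0.00726 by fry. Class I genes are near-identical in sequence, so the split of reads among H2-Q6, H2-Q7 and H2-Q9 is uncertain. The class II list did not pass, with 0 of 10 members past the threshold, 3 higher over the list alone and a median log2 fold change of 0.33 (camera adjusted p = 0.105).

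Among the other large rises, Iigp1, an immunity-related GTPase, rose from 12.5 ± 0.0976 to 98.4 ± 8.67 CPM (SD, n = 2 each), or 7.88-fold, with an adjusted p of 6.3e-05. Tgtp2, a GTPase of the same kind, rose 11.6-fold and Slfn4, of the Schlafen family, 11.8-fold. Both Tgtp2 and the class I gene H2-Q9 have close paralogs, and H2-Q9 had 5 counts in each ff library against 136 and 113 in ko. Cxcl9, a chemokine induced by interferon gamma, had 15 counts over the ff group (2 and 13) and 336 over the ko group, a ratio of 19.9 with an exact counting interval of 11.9 to 35.9. Its log2 fold change was 4.28, and 3.55 without ff library 2 and 6.03 without ff library 5. Ccl5, a chemokine, had 12 (2 and 10) and 173 counts, a ratio of 12.8 (7.15 to 25.3), and its log2 fold change was 3.65, 2.98 without ff library 2 and 5.08 without ff library 5. Gzma, a protease of cytotoxic lymphocytes, had 5 and 90 counts, a ratio of 16.0 (6.60 to 50.4). With limma-voom these 3 genes missed the threshold, with adjusted p of 0.0629 for Cxcl9, 0.0529 for Ccl5 and 0.0503 for Gzma. Of genes named below, Selplg, Aif1, Igf1, Lgals3, Tk1, Birc5, Icam1, Rpl11, Daxx, Plk2, Ccr2, Zdhhc22 and LOC118567825 also missed it with limma-voom. Their adjusted p lay between 0.0503 and 0.0826 by that test. Igf1 also missed it with the filter of 50 counts, at an edgeR adjusted p of 0.0505.

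**Figure D2:**
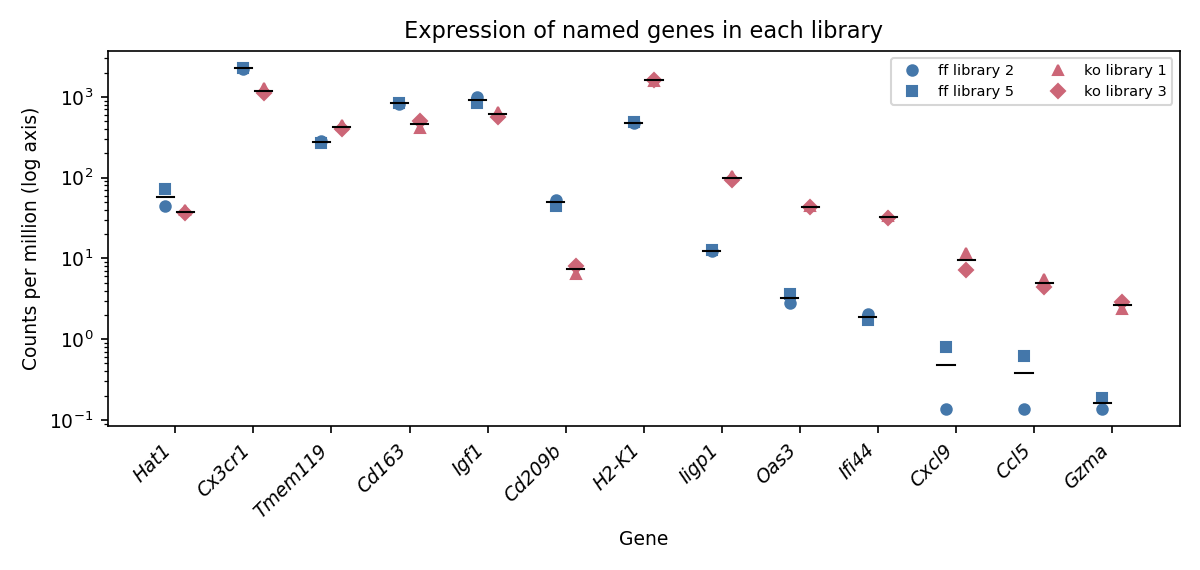
CPM on a log axis for 13 named genes, with 1 point per library (blue circle and square, ff libraries 2 and 5; red triangle and diamond, ko libraries 1 and 3) and a black bar at each group's mean. Cx3cr1 lies at 2265 in ff and 1198 in ko, Oas3 at 3.23 and 43.4, and for Hat1 the ff libraries lie apart at 44.3 and 71.4.

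Markers of microglia themselves did not move as a group, but single ones did. Cx3cr1, the fractalkine receptor, fell from 2265 ± 39.0 to 1198 ± 107.4 CPM (SD, n = 2 each), a log2 fold change of -0.92 ± 0.08 (SE) with an adjusted p of 0.00108. Tmem119, a marker of mature microglia, rose from 276.6 ± 9.90 to 422.7 ± 39.4, and the protease Ctss rose from 635.3 ± 0.820 to 900.2 ± 10.5 (adjusted p = 0.0123, and 0.0592 with an offset for transcript length and GC content). Of 22 tested homeostatic genes 3 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 0.03 (camera adjusted p = 0.503). Selplg, the third to rise, had an adjusted p of 0.0329, and of 0.136 without ff library 2. Of 19 genes shared by microglia and other macrophages 4 rose and 0 fell, against 5 and 2 over the list alone. Those 4 were Fcgr1, Aif1, Coro1a and Lyz2, between 1.36-fold and 1.44-fold higher. Without ff library 2 the adjusted p was 0.0549 for Fcgr1, 0.138 for Aif1 and 0.0931 for Coro1a. It was 0.0551 for Coro1a without ko library 1, and 0.0654 for Lyz2 without ff library 5. Among genes of axon tract-associated microglia, Itgax fell from 65.3 ± 6.96 to 33.8 ± 6.21 and the growth factor Igf1 from 915.7 ± 98.4 to 607.3 ± 66.7. The galectin genes Lgals1 and Lgals3 rose 1.39-fold and 1.38-fold. Of these 20 genes 2 rose and 2 fell, against 3 and 3 over the list alone (camera adjusted p = 0.710). Igf1 had an adjusted p of 0.0436, and of 0.0796 without ff library 2. Without ff library 2 it was 0.0527 for Lgals1 and 0.106 for Lgals3, and without ff library 5 it was 0.0617 for Lgals3. With the length and GC offset Selplg, Aif1, Coro1a, Lyz2, Igf1, Lgals1 and Lgals3 missed the threshold, with adjusted p between 0.0594 and 0.159.

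Among the deepest falls, Cd209b, a C-type lectin that binds microbial sugars, fell from 49.4 ± 5.96 to 7.29 ± 1.20 CPM (SD, n = 2 each), a log2 fold change of -2.76 ± 0.16 (SE) with an adjusted p of 0.000184. Cd209d fell from 5.87 ± 0.487 to 1.28 ± 0.296 and Cd209g from 52.5 ± 10.9 to 18.6 ± 3.81, and reads may be split among these paralogs. Cd209f, of the same family, is in the border-associated macrophage list, and its log2 fold change of -1.18 did not pass the threshold. Capn11, a calpain protease, had 108 and 74 counts in ff and 3 and 1 in ko, so that ff exceeded ko 51.2-fold with an exact counting interval of 19.7 to 190.0. Its log2 fold change was -5.61, and -6.40 without ko library 1. Gpr165, an orphan receptor gene, fell from 81.5 ± 2.75 to 32.5 ± 1.23, and Atp6v0d2, a subunit of the vacuolar proton pump, from 91.7 ± 2.88 to 44.2 ± 5.30. Ankrd23, the potassium channel gene Kcnj2, the palmitoyltransferase gene Zdhhc22 and LOC118567825 also fell, to between 0.402 and 0.494 of their ff level. Without ff library 2 those 4 missed the threshold, with adjusted p of 0.0793, 0.0539, 0.142 and 0.0803, and LOC118567825 also missed it without ff library 5, at 0.135.

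Of the border-associated macrophage list, only Cd163, a scavenger receptor for haptoglobin and haemoglobin, passed among 16 tested genes. It fell from 831.1 ± 12.9 to 455.5 ± 58.4 CPM (SD, n = 2 each) with an adjusted p of 0.0040. When adjusted over the list alone 2 genes rose and 6 fell. The median log2 fold change was -0.21 (95% interval -0.37 to 0.03), with a camera adjusted p of 0.0357 and an adjusted p of 0.849 with an estimated correlation. Without ff library 2 the list's median was -0.12 with a camera adjusted p of 0.234, without ff library 5 the median was -0.33, and without ko library 1 the adjusted p was 0.297.

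Markers of other cell types were measured in the same libraries. The border-associated macrophage list had a mean log2 CPM of 9.301 and 9.174 in ff libraries 2 and 5, and 8.939 and 9.155 in ko libraries 1 and 3. For the homeostatic microglia list it was 7.921, 7.996, 8.069 and 7.958 in that order. Slc1a3 and Aqp4, the most expressed of the neural progenitor and of the oligodendrocyte and astrocyte lists, had means of 497.2 and 253.1 CPM. In each library the mean of the border-associated macrophage list lay above that of the homeostatic microglia list. The lists hold different genes, so this gives no share of cells. The isolates thus held transcripts of genes listed as markers of other cells, and changes are not assigned to a cell type. Lymphocyte markers had a median log2 fold change of 0.66 over 17 genes, of which 1, Gzma, rose, against 7 over the list alone (camera adjusted p = 1.44e-06). Markers of mural cells and fibroblasts had a median of 0.77 over 17 genes, with 0 past the threshold by either adjustment (camera adjusted p = 0.00585). In these, Col1a1 had 130.5 ± 50.8 CPM in ko and 77.7 ± 22.5 in ff (SD, n = 2 each). Neuronal markers had a median of -0.26 over 28 genes, of which 1, the transcription factor gene Sox11, fell from 188.2 ± 3.65 to 121.4 ± 4.46, against 2 over the list alone (camera adjusted p = 0.00303). With an estimated correlation the adjusted p was 0.712 for each of these 3 lists. The lymphocyte median was 0.40 without ff library 5 and 0.93 without ff library 2. The mural median was 0.48 without ff library 2, with an adjusted p of 0.184, and 0.42 without ko library 1. The neuronal median was -0.13 without ff library 5, with an adjusted p of 0.0662, -0.10 without ko library 1, with an adjusted p of 0.121, and -0.51 without ko library 3. Neural progenitor (0.08), oligodendrocyte and astrocyte (-0.09) and endothelial (0.33) markers did not pass, with their median log2 fold changes in parentheses and 0 genes past the threshold by either adjustment. Nor did those of monocytes, neutrophils and mast cells, whose median was 0.28 and whose mean was -0.21, with 2 genes higher and 1 lower over the list alone. In that list Ccr2, a chemokine receptor, rose from 42.2 ± 1.82 to 60.3 ± 1.09, with an adjusted p of 0.0405, of 0.0934 without ff library 2 and of 0.127 without ff library 5. Erythroid and sex-linked markers, with 4 and 1 tested genes, were not tested as lists.

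**Figure D3:**
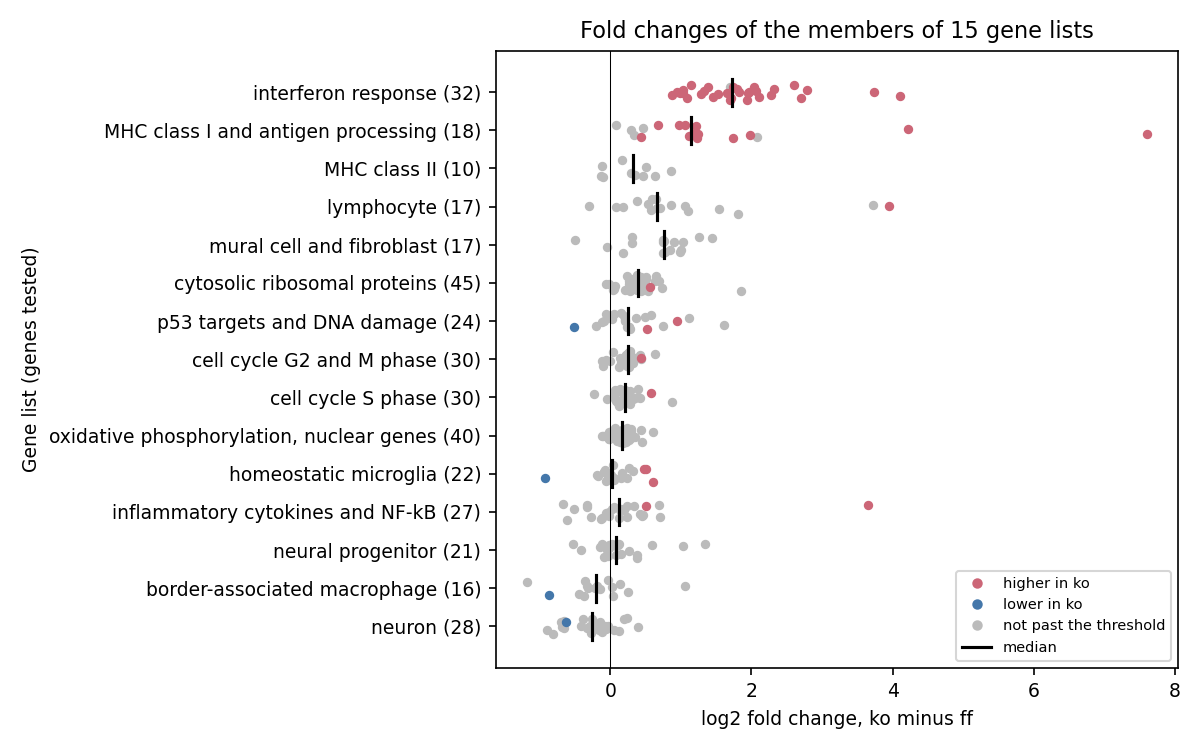
Each point is 1 tested gene of 15 gene lists, placed by its log2 fold change of ko minus ff, with the number of genes tested in parentheses and a black bar at the list's median. Interferon response and class I genes lie to the right, at medians of 1.73 and 1.14, while the neuron and border-associated macrophage lists have medians of -0.26 and -0.21, and the point above 7 is the fitted value of H2-Q6, which had 0 counts in ff.

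Several lists of growth and stress genes shifted by small amounts. Cytosolic ribosomal protein genes had a median log2 fold change of 0.40 over 45 genes, with Rpl11 past the threshold and 26 higher over the list alone (camera adjusted p = 1.67e-10, and 0.783 with an estimated correlation). With an offset for transcript length and GC content the median was 0.25. Their share of all counts was 0.566% and 0.671% in ff libraries 2 and 5, and 0.883% and 0.782% in ko libraries 1 and 3. Cell cycle genes had medians of 0.25 in the G2 and M phase list and 0.20 in the S phase list, with 1 of 30 genes past the threshold in each, Birc5 and Tk1, against 5 and 1 over the lists alone. Their camera adjusted p were 9.67e-05 and 0.000158, and 0.796 and 0.712 with an estimated correlation. The G2 and M median was 0.11 without ff library 2, with an adjusted p of 0.039, and 0.35 without ff library 5. Nuclear genes of oxidative phosphorylation had a median of 0.16 over 40 genes with a count of 0 past the threshold by either adjustment (camera adjusted p = 0.000463), as had antioxidant genes, at 0.19 over 19 genes (camera adjusted p = 0.0357). With an estimated correlation both had an adjusted p of 0.712, and with the length and GC offset they had 0.286 and 0.0868, at medians of 0.03 and 0.11. Of 24 tested p53 targets, the cell cycle inhibitor Cdkn1a rose from 52.4 ± 2.49 to 100.5 ± 2.86 CPM (SD, n = 2 each) with an adjusted p of 0.00117. The apoptosis gene Bax rose 1.43-fold and the kinase gene Plk2 fell to 0.701 of its ff level, and these were also the 3 calls over the list alone (camera adjusted p = 0.0149, and 0.712 with an estimated correlation). The p53 list had an adjusted p of 0.0704 without ff library 5 and of 0.121 without ko library 1, where its median was 0.13. The antioxidant list had 0.184 without ff library 2, 0.0551 without ff library 5 and 0.210 without ko library 1, where its median was 0.09. Without ff library 2 the adjusted p was 0.121 for Rpl11, 0.223 for Birc5, 0.196 for Tk1 and 0.121 for Plk2, and it was 0.0826 for Birc5 without ff library 5. With the length and GC offset Bax had 0.291, Rpl11 0.0831, Birc5 0.0701 and Tk1 0.070.

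Of the remaining lists, none passed camera. Among complement and phagocytosis genes Axl, a receptor tyrosine kinase, rose from 65.3 ± 0.254 to 128.5 ± 6.57 CPM (SD, n = 2 each) and the Fc receptor gene Fcgr4 from 29.8 ± 2.41 to 56.3 ± 3.24. In that list 3 rose and 1 fell among 31 genes, against 5 and 5 over the list alone, with a median log2 fold change of 0.06. Inflammatory cytokine and NF-kB genes had 2 of 27 higher, Ccl5 and Icam1, against 3 higher and 1 lower over the list alone, with a median of 0.12. Icam1 had an adjusted p of 0.0288, of 0.115 without ff library 2 and of 0.0594 with the length and GC offset. Among enzymes of histone acetylation Hdac4, a histone deacetylase, fell from 108.4 ± 1.71 to 69.6 ± 7.97, the only 1 of 26 genes past the threshold, against 1 higher and 2 lower over the list alone and a median of -0.04. Among 24 chromatin assembly genes the chaperone gene Daxx rose 1.38-fold, with an adjusted p of 0.0474, of 0.061 without ff library 2, of 0.149 without ff library 5 and of 0.10 with the length and GC offset. That list had 4 genes higher over the list alone and a median of 0.15. Secreted factors acting on neural progenitors had a median of 0.16 over 41 genes, with Igf1 alone past the threshold and 1 higher and 1 lower over the list alone. Lysosomal genes had a median of 0.01 over 31 genes, with Atp6v0d2 alone past it and 3 higher and 2 lower over the list alone.

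No gene passed in the lists of cholesterol synthesis, lipid metabolism, glycolysis, mitochondrial genome, replication-dependent histones, unfolded protein response, hypoxia, immediate early or TGF-beta genes. Their median log2 fold changes were -0.07, -0.03, -0.06, 0.09, 0.19, -0.01, -0.06, -0.01 and 0.05 in that order, and the count past the threshold was 0 in each. Over the lists alone 2 lipid genes were higher and 1 lower, and 1 gene was lower in each of the glycolysis, hypoxia and immediate early lists. Replication-dependent histone mRNA mostly lacks a poly(A) tail, and these libraries were made from poly(A) RNA. Of the 37 members of that list 16 were tested, so its result says little about these genes. Apoe, the most expressed of the lipid genes, lay at 15520 ± 449.6 CPM in ff and 18420 ± 345.0 in ko (SD, n = 2 each) with an adjusted p of 0.124. Median and mean differed in sign in the lipid and unfolded protein lists, and median and camera direction in the lysosome and lipid lists.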

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

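The offset for transcript length and GC content was chosen after the data were seen, and all other alternatives before the data were examined. The 270 calls (188 higher, 82 lower) became 566 with DESeq2 (341 and 225), 175 with limma-voom (131 and 44), 1386 without a filter (779 and 607) and 110 with a fold of at least 2 (97 and 13), and the cause was not tested. Without scaling factors 142 genes were lower and 222 higher, and with DESeq2 size factors 92 and 186. The share of calls that were higher was 69.6%, against 61.0% without scaling factors and 66.9% with DESeq2 size factors. It was 60.25% with DESeq2, 74.86% with limma-voom and 56.2% without a filter. Lower calls outnumbered higher ones without ff library 5 and without ko library 1. Leaving out 1 library gave 198 to 1213 calls, 143 to 860 higher and 55 to 585 lower. The lowest was without ff library 2, the highest total without ko library 3 and the most lower genes, 585, without ko library 1. In these fits the lone library of a group is assumed to vary like the other group. The length and GC offset gave 157 higher and 100 lower. Hat1 stayed negative in every alternative. It passed without a filter (-0.61, adjusted p = 2.3e-05), and ran from -0.91 to -0.25 with a library left out, with adjusted p from 2.3e-05 to 0.612 over its alternatives. Of 35 lists, 12 passed camera with the preset correlation, 0 with an estimated correlation (limma, 2 at an unadjusted p under 0.05) and 2 by fry. The lists of other cell types past the threshold numbered 4, and 2 to 5 with a library left out, the 2 without ff library 2. The gap between the mean correlation within and between groups was 0.0076, and 0.0979 over the 500 most variable genes. The fold threshold of 2 is left out of the tally of named genes that follows. Some of those genes did not reach it, such as Cx3cr1 with a log2 fold change of -0.92. Of 51 named genes past the threshold apart from Hat1, 26 passed in every alternative that gave a value and 25 missed it in at least 1. For 20 of these a single left-out library was enough, and 0 changed direction. No paired analysis was run. The labels give no litter, and the titles, numbered 1 and 3 in ko and 2 and 5 in ff, do not tell whether libraries are paired. The alternatives planned for FPKM values and for a table of the authors' own comparison were not run, since the table holds counts. With 2 libraries per group, 29.9% of simulated changes of 1.5-fold were recovered, so changes of that size may be missed at this depth.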

Other observations

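Gene families were defined by symbol after the data were seen, with 1 rule for all families and none picked by hand. Of 458 families with at least 5 tested members, 7 held more higher genes and 2 more lower genes than the rest by a one-sided Fisher's exact test, adjusted over 916 tests. The guanylate-binding proteins (Gbp), GTPases that act on intracellular microbes, had 6 of 10 members higher (adjusted p = 2.39e-07). The Schlafen genes (Slfn) had 5 of 8 higher (adjusted p = 3.71e-06) and the Parp genes, of ADP-ribosylation, 4 of 12 (adjusted p = 0.00101, but 0.282 without ff library 2 and 0.157 without ko library 3). Symbols that begin with Lgals, for galectins and a protein that binds them, had 4 of 6 higher (adjusted p = 3.7e-05), but 2 without ff library 2 (adjusted p = 0.0903) and 2 with the length and GC offset (adjusted p = 0.144). The Ifi, Ifit and Oas families, which overlap the interferon list, had 10 of 16, 4 of 5 and 4 of 6 higher. Slfn5, of the Schlafen genes, is in that list too. Whether the other families rose apart from the interferon response was not tested. The Cd209 lectins had 4 of 7 members lower (adjusted p = 5.28e-06), and the Klhl genes 3 of 30 (adjusted p = 0.04995, but 0.444 without ff library 5 and 0.925 with the length and GC offset). Members of a family share sequence and some share reads, so their calls are not independent.

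Few counts came from interferon genes themselves. Ifnk had 13 and 5 counts in ff libraries 2 and 5 and 10 and 0 in ko libraries 1 and 3. Ifnb1 had 1 count in ff library 5 and 1 in ko library 3, and Ifna2, Ifna13 and Ifnz had at most 1 count in any library. Ifng had 0 counts in both ff libraries and 7 and 5 in ko libraries 1 and 3, over the group 3.55-fold the floor of 3 counts. These genes were chosen after their values were seen.

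More natural killer cells in the ko isolates are a hypothesis that was raised by the calls of Gzma, Klrc1 and Ccl5, and both its marker list and its test were chosen after those were seen. The test was also written when the median it measures was already known, so it is no independent evidence. The 12 other tested markers had a median log2 fold change of 1.5531 (95% interval 0.42 to 1.77), which leaves the hypothesis open. Their rise may also come from induction in other cells, which was not tested. Over 27 markers the summed level was 13.6 and 17.7 CPM in ff libraries 2 and 5, and 37.3 and 41.9 in ko libraries 1 and 3. These CPM are on library totals without scaling factors, and the 27 markers include Gzma, Klrc1 and Ccl5. The most abundant were Il18rap, at 64 and 113 counts in ff and 103 and 78 in ko, Ccl5, at 2 and 10 against 103 and 70, and Ctsw, at 25 and 25 against 64 and 63. The log2 fold changes of Il18rap, Itga2 and Txk were -0.13, -0.36 and -0.01. The list holds 4 genes of the lymphocyte list.

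Of the tests in the 3 paragraphs that follow, those of sex, of the microglial share and of a replaced Cx3cr1 copy were chosen after the result was seen, as were the summed levels. The tests of length and GC bias rest on an offset that was added after the data were seen. Intervals of list medians there leave out the spread between libraries. The interferon response rose in both ko libraries, the 1 with Y-linked counts and the 1 without. Sex as the cause is argued against, since it needs a median log2 fold change under 0.8643 without ko library 1, where it was 1.6671 (95% interval 1.43 to 1.92), and length or GC bias by a median of 1.6808 (1.39 to 1.94) after correction, against the same bound. The pooled markers of monocytes, neutrophils, mast cells and lymphocytes had a median of 0.5419 (95% interval 0.28 to 0.64), below the 1.45 lower bound of the interferon list. This argues against a joint gain of these cells, carrying the transcripts themselves, as the cause of the whole rise. A pooled median can hide a gain of a single cell type, and it cannot test induction in other cells by a few immune cells. The summed level of the interferon list was 1220 and 1200 CPM in ff libraries 2 and 5 and 3421 and 3334 in ko libraries 1 and 3, against 745 and 663.4, and 755.4 and 783, for the pooled markers. A part from natural killer cells, few of whose genes are among the pooled markers, deletion of Hat1, the presence of Cre, and litter stay open and untested, so the rise is at most a candidate effect of the genotype.

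Cx3cr1 lay at 0.529 of its ff level. A lower share of microglia needs other homeostatic markers to fall too, and their median log2 fold change was 0.0442 (95% interval -0.04 to 0.17). Replacement of 1 of 2 gene copies, as in a Cre knock-in at Cx3cr1, cannot be told apart from other causes: the interval of the change, -0.9191 (-1.11 to -0.73), holds -1, but that idea was taken from the size of the fall and the labels name no Cre driver. An effect of the genotype on Cx3cr1 stays open as well.

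Genes lower in ko had longer transcripts, with a median of 4715 nt against 3360 nt in genes not called and 2590 nt in higher genes. Over the 14135 genes not called and of known length, the log2 fold change also fell with length (Spearman correlation -0.192). For the difference between the libraries of a group this correlation was 0.0018 in ff and -0.0102 in ko. Why the trend followed the groups was not tested. Length or GC bias as the whole cause is argued against, since 66 of 79 lower genes with a known length kept their call after correction, and their median log2 fold change was -0.64 after and -0.66 before it. Fewer border-associated macrophages cannot be told apart from other causes, since the median of their markers was -0.2063 with an interval that reaches 0.03. Cd209b and Capn11 fell much further than that median, and what lowered them was not tested. Log2 fold changes of members of the border-associated list ran from -1.18 for Cd209f, of the Cd209 family, to 1.06 for Siglec1, neither past the threshold. An effect of the genotype on the lower genes stays open and untested.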
